A study of Mus musculus with 12 samples.

How the data were processed

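RNA from regulatory T cells (Tregs) was sequenced in 12 mouse libraries, 3 for each combination of genotype (Wt or Lag3-deficient) and tissue of origin (pancreatic islets or non-draining lymph nodes, NDL), taken in a model of autoimmune diabetes. The labels gave the genotype, the tissue and a replicate number. They described the material as cytoplasmic RNA, with total RNA as the molecule. Nothing in the labels says that the replicates of a group came from separate animals, so every p-value measures the spread between these samples, which may be technical. The sorting markers, library kit and strandedness are not given in the sources used here. TopHat2, DESeq2 and the genome build mm10 are named, without versions or roles, in the submitters' processing notes.

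Values were deposited as 2 gene tables. The first deposited table lists 23361 gene symbols, and its values are a signal in the form of rescaled counts, although whole numbers. The 12 columns sum to between 15232498 and 15370098, a spread of 0.899%, where raw sequencing depths would differ. Several columns skip whole numbers at regular steps, as counts multiplied by a factor and rounded do. The factor could be resolved for 5 libraries. It was 2.79 for Lag3 islet 2 (about 5.5 M reads before scaling), 1.58 for Wt NDL 2 (9.7 M), 1.11 for Lag3 NDL 1b (13.8 M), 0.863 for Lag3 NDL 2 (17.8 M) and 0.797 for Lag3 islet 1b (19.1 M). For the other 7 libraries the depth is unknown. In a simulation of known factors, 7 of 9 were recovered within 3%. Scaling and rounding hide the sampling noise of shallow libraries and give no basis for counting intervals, so none are given. Levels are given in CPM, and 1 CPM equals about 15.3 rescaled counts. The second deposited table holds 10317 of these genes as a signal whose sorted values are nearly the same in all 12 columns, a form that quantile normalization gives. Its method and gene filter are not given in the sources used here. It is at 0 exactly where the first table is at 0 (0 mismatches), and the lowest Spearman correlation between the tables within a library was 0.992. It served as an alternative input.

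Each group has columns numbered 1, 2 and again 1 in the headers, while the sample titles run from 1 to 3. The genotype and tissue are clear from the column names. The repeated number is written here as 1a for its first occurrence and 1b for its second. The 4 columns called 1b, 1 per group, held 1.26 to 1.68% of their signal in the ribosomal RNA gene Rn45s, against 0.149 to 0.571% in the other 8.

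Analysis used limma 3.58.1 in R 4.3.3, with statmod 1.5.0. A count model had been chosen before the data were examined. As the values turned out not to be raw counts, limma with a mean-variance trend was used on log2(CPM + 1), and a fold change on this scale understates the change of weakly expressed genes. Scaling was by trimmed means of log ratios, TMM, trimming 30% of ratios and 5% of levels. Genes with at least 10 rescaled counts in at least 3 libraries were tested (10868 of the 21708 above 0), in 1 linear model with the 4 groups as terms, no covariates and 8 residual degrees of freedom before moderation. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was the threshold. The 6 planned comparisons were Lag3-deficient against Wt in islets, in NDL and averaged over both tissues, islet against NDL in each genotype, and the difference of the genotype effect between tissues. Islet against NDL averaged over both genotypes was added after the data were seen. Log2 fold changes are given ± SE and levels as mean CPM ± SD, with n = 3 libraries per group. A value of 0 in the table is reported as listed at 0, with each library's value and no fold against a group with all libraries at 0.

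Gene lists had been fixed before the data were examined. There were 19, for Treg identity, effector Tregs, IL-2 and STAT5 signalling, proliferation, inhibitory receptors, naive cells and lymph node recirculation, the early response to T cell receptor (TCR) stimulation, effector T cell cytokines, chemokines and integrins, the interferon response, glycolysis, apoptosis regulators, heat shock, and markers of endocrine, exocrine, B, myeloid, CD8 and NK, and stromal cells. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Some genes stand in more than 1 list. Of the listed symbols, 2 of 16 endocrine, 13 of 15 exocrine, 8 of 14 B cell and 6 of 14 myeloid markers could be tested. So could 4 of 10 CD8 and NK markers, 4 of 12 stromal markers and 8 of 19 effector cytokine genes. The genes named were Lag3, the 10 largest changes per direction past the threshold with an average log2 level of at least 4 and libraries that did not overlap, up to 4 members of each list with the smallest p, and, where fewer than 10 genes qualified, the 10 smallest p at that level. Predicted genes and immunoglobulin, T cell receptor or ribosomal protein genes were counted but not named. Genes outside this rule are said to be chosen after their values were seen. The single-gene result of 1 list member is not reported here.

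In simulated data at the real levels and spread, 200 genes with an average log2 level of at least 4 were changed. Changes in weaker genes were not simulated. The Lag3-deficient against Wt islet comparison recovered 0% of 2-fold, 14.5% of 4-fold and 50.5% of 8-fold changes (10824, 10825 and 10824 genes tested). In these, 0, 5 and 6 other genes were called. The islet against NDL comparison in Wt recovered 0.5%, 16% and 55.5% (10815, 10825 and 10815 genes), with 0, 1 and 6 others called. A 2-fold shift of the proliferation list was called in both comparisons, with 1 and 0 of the 18 other lists called beside it. The simulated genes varied independently of each other. The simulation therefore cannot show how the list test behaves where the genes of a list vary together.

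Alternatives were RLE size factors, totals as deposited, no filter or a filter of 50, a replicate block, robust moderation, a test against a fold of 1.5, voom with sample weights, the groups of a comparison alone, the second table, pseudocounts of 0.25 and 4, a term for the 1b columns or their omission, omission of the 3 libraries scaled up, and omission of each library in turn. Positions came from GENCODE release M21 on GRCm38, the assembly also called mm10, where 21725 symbols of the first table were found. Reads, alignments and the animals' data were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.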

Results

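Gene expression was compared in 12 libraries of Tregs, the Foxp3-dependent CD4 T cells that restrain immune responses. Cells were Wt or deficient in Lag3, an inhibitory surface receptor that binds MHC class II, and came from islets, the target of the autoimmune attack, or from NDL. Each of the 4 groups had 3 libraries, called 1a, 2 and 1b. The deposited totals lay between 15232498 and 15370098 rescaled counts in all libraries, so sequencing depth cannot be read from them. Libraries of a group correlated at Spearman 0.661 to 0.733 in Lag3-deficient islets, 0.757 to 0.785 in Wt islets, 0.718 to 0.882 in Lag3-deficient NDL and 0.723 to 0.801 in Wt NDL. The median residual SD of a gene was 1.26 log2 units.

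The targeted gene, Lag3 (chromosome 6, 124904361 to 124911705, minus strand, GRCm38), was listed at 40, 48 and 120 rescaled counts in Wt islet libraries 1a, 2 and 1b. In Lag3-deficient islet libraries it was listed at 1, 0 and 0. Wt NDL libraries held 2, 5 and 6 and Lag3-deficient NDL libraries 1, 0 and 3. The level in Wt islets was 4.81 ± 2.91 CPM. The log2 difference between genotypes was -2.39 ± 0.62 in islets, with all 3 Lag3-deficient libraries below all 3 Wt libraries, an unadjusted limma p of 0.00106 and an adjusted p of 0.85. In NDL it was -0.24 ± 0.62 (adjusted p = 1), and between islets and NDL in Wt cells 2.07 ± 0.62 (adjusted p = 0.283). Without any 1 of the Wt islet libraries the gene fell under the filter, and no value was given. The size of the islet difference depended on the pseudocount, as given with the alternatives.

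**Figure D1:**
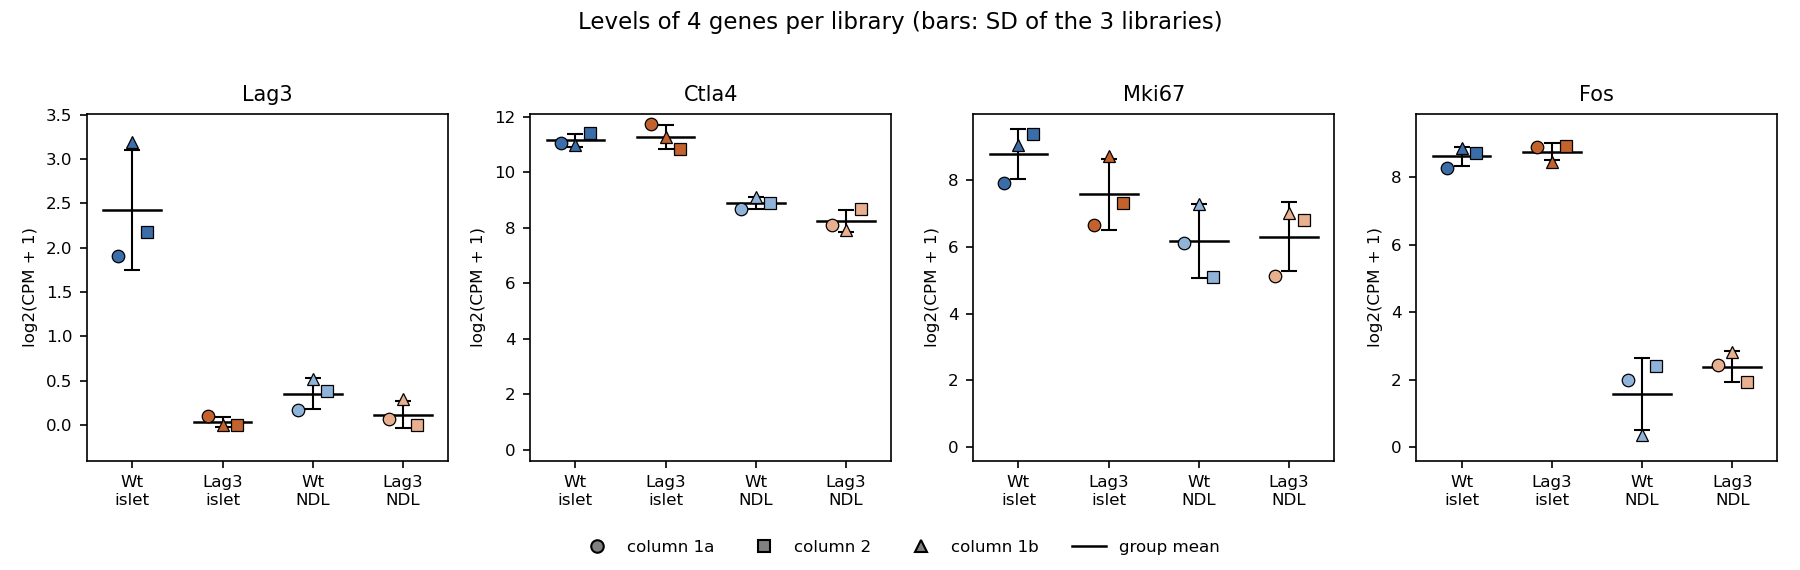
Levels of Lag3, Ctla4, Mki67 and Fos as log2(CPM + 1) in the 12 libraries, with markers for columns 1a, 2 and 1b, horizontal lines for group means and bars for the SD (n = 3 per group). Ctla4 and Fos lie higher in all 6 islet libraries than in all 6 NDL libraries, and Lag3 lies above the other groups in Wt islets.

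The first question was whether Lag3 deficiency altered the transcriptome of Tregs in the islets, where the series title places an effect on proliferation and function. The 42 proliferation genes averaged 5.19 ± 0.73 log2 units in Lag3-deficient and 5.59 ± 0.29 in Wt islet Tregs. Mki67, a marker of cycling cells, measured 226 ± 170 against 475 ± 213 CPM (log2 difference -1.21 ± 0.67, adjusted p = 0.926). The replication licensing gene Mcm6 measured 189 ± 145 against 366 ± 164 CPM (-1.15 ± 0.57, adjusted p = 0.877), and Mcm4 64.3 ± 18.4 against 138 ± 24.0 CPM. The list had 14 of 42 members with a positive fold change, a median of -0.42 and a camera adjusted p of 0.857. Of its members, 0 passed over all genes and 0 adjusted over the list alone. An exact two-sided permutation test of the list mean gave p = 0.4, where 3 against 3 libraries cannot go below 0.1. The median over all tested genes was -0.22 in this comparison, -0.03 with RLE size factors, -0.02 without Lag3 islet 2, a library scaled up 2.79-fold, -0.37 without Lag3 islet 1b and -0.38 without the 1b columns. The proliferation list averaged 4.79, 4.75 and 6.04 log2 units in Lag3-deficient islet libraries 1a, 2 and 1b.

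Of the tested members of the Treg identity and effector Treg lists, 0 passed over all genes or adjusted over the list alone. Foxp3, the lineage factor, measured 349 ± 130.0 in Lag3-deficient and 400.5 ± 68.0 CPM in Wt islet Tregs (-0.25 ± 0.40, adjusted p = 0.995, chosen after its values were seen). The Treg identity list had 11 of 19 positive members, a median of 0.11 and an adjusted p of 0.805. Within it Ikzf4, which encodes the Foxp3 partner Eos, was at 8.14, 68.2 and 69.4 CPM in Lag3-deficient libraries 1a, 2 and 1b and at 6.83, 8.73 and 5.08 CPM in Wt (2.19 ± 1.05, adjusted p = 0.869). The effector Treg list had 13 of 29 positive members and an adjusted p of 0.857, with a negative median and mean and a test in the positive direction. Its member Tnfrsf9, an activation receptor, differed by -1.31 ± 0.98. Cish, a target of IL-2 and STAT5 signalling, differed by -0.78 ± 0.54 (adjusted p = 0.947), and the interferon-induced genes Stat2 and Isg20 by -2.18 ± 0.99 and -2.47 ± 1.14 (adjusted p = 0.851 for Isg20). Actn1, of the naive cell list, differed by -2.35 ± 0.98. Among inhibitory receptors 1 gene, Lag3 itself, passed when adjusted over the list alone, and 0 passed over all genes.

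Exocrine pancreas markers, which encode digestive enzymes, fell in Lag3-deficient islet libraries as a list (camera adjusted p = 3.24e-05, 0 of 13 members positive, median -2.72). The call was lost with an estimated correlation (adjusted p = 0.959). Cpb1 differed by -3.64 ± 1.17, Reg1 by -3.56 ± 1.30 and Cpa1 by -3.01 ± 1.23 (adjusted p = 0.85 for each), and 0 members passed over all genes or adjusted over the list alone. The summed level was 3362, 181 and 843 CPM in Wt islet libraries 1a, 2 and 1b and 643, 34.1 and 327 CPM in Lag3-deficient ones, and an exact two-sided permutation test of the list mean gave p = 0.3. The list did not pass without Lag3 islet 2 (adjusted p = 0.123) or Wt islet 1a (0.109). Of the 18 other lists 0 passed, with adjusted p-values from 0.229 for stroma markers to 0.971 for apoptosis regulators. Median, mean and test also differed in sign for the naive, early TCR, effector cytokine, chemokine, glycolysis, heat shock and myeloid lists.

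Single genes with the smallest p and a level above the limit were mostly lower in the Lag3-deficient islet libraries, and 0 of 10868 passed with limma. Filip1l differed by -4.19 ± 1.00, Fnta, a subunit of protein farnesyltransferase, by -4.20 ± 1.05, Xpot, a tRNA exporter, by -3.53 ± 0.89, and Cript by -2.38 ± 0.61 (51.7 ± 43.3 against 206 ± 37.1 CPM). Ppcs, Strbp, Exoc5, Pex2 and Jkamp differed by -3.84 ± 0.99, -3.27 ± 0.86, -3.80 ± 1.02, -4.08 ± 1.11 and -3.45 ± 0.95, and AI837181 was the 1 with a positive value (3.10 ± 0.87). Each of these 10 had an adjusted p of 0.85. The smallest adjusted p, 0.364, belonged to the homeobox gene Hmbox1 (4.11 ± 0.77), chosen after its values were seen, which measured 18.9, 16.0 and 28.5 CPM in the Lag3-deficient islet libraries and at most 0.690 CPM in any other library. At an unadjusted p under 0.05 there were 624 genes (135 higher, 489 lower) where 543 would arise by chance. At that threshold 975 were found without Lag3 islet 1b and 1063 without the 1b columns. Lag3 islet 2 had 927 tested genes listed at 0, where the other islet libraries had 404 to 513. Its TMM and RLE factors also disagreed, at 1.18 and 0.786. The excess of lower genes is therefore not taken as a direction of the genotype effect. The count past the adjusted threshold was 0 also with voom weights (463 at the unadjusted threshold) and against a fold of 1.5 (352). Libraries of the genotypes did not overlap for 1013 genes, 9.32% where chance gives 10%. Without Lag3 islet 1b, 16 genes passed, 4 higher and 12 lower, among them Fnta, Ppcs, Exoc5, Filip1l, Cript and Hmbox1.

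In NDL, the comparison asked whether Lag3 deficiency mattered outside the inflamed tissue. The tested markers of CD8 T cells and NK cells rose in Lag3-deficient NDL libraries as a list (camera adjusted p = 0.029, 4 of 4 tested members positive, median 1.55), and the call was lost with an estimated correlation (adjusted p = 0.233). Only 4 of the list's 10 genes were tested, and Gzmk, Klrd1, Klrk1, Gzma, Ncr1 and Klrb1c fell below the filter. The call therefore stands on few markers and says little of NK cells. Nkg7, a cytotoxic granule gene of the list, measured 77.1 ± 32.2 against 24.6 ± 5.11 CPM (1.53 ± 0.70), and 0 members passed over all genes or adjusted over the list alone. Cd74, the invariant chain of MHC class II, measured 85.5 ± 38.5 against 23.6 ± 20.2 CPM (2.39 ± 0.76) and was the 1 B cell marker that passed when adjusted over the list alone. Atp6v1h, a subunit of the vacuolar proton pump, measured 103 ± 46.3 against 16.5 ± 10.8 CPM (2.67 ± 0.66). Fam46a differed by -1.79 ± 0.50, the replication genes Orc6 and Mcm7 by -3.26 ± 0.98 and -1.92 ± 0.66, the cysteine desulfurase gene Nfs1 by 3.69 ± 1.17 and Ctla4 by -0.65 ± 0.34. All these genes had an adjusted p of 1. Proliferation genes had 25 of 42 positive members and a median of 0.06 (camera adjusted p = 0.582), and the other lists had adjusted p-values from 0.17 to 0.994, with medians and tests of opposite sign for effector cytokines and glycolysis. With limma 0 genes passed (296 at an unadjusted p under 0.05, 155 higher and 141 lower, and 487 without Wt NDL 1a), with voom weights 0 (450) and against a fold of 1.5 0 (153). Libraries did not overlap for 818 genes (7.53%, chance 10%). The CD8 and NK list did not pass without Lag3 NDL 1a (adjusted p = 0.159), Wt NDL 1a (0.128) or Wt NDL 1b (0.129), without the 1b columns (0.138) or without the 3 libraries scaled up (0.0591), and 2 lists passed without Wt NDL 2 or Lag3 NDL 1b.

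Averaged over both tissues, Lag3 differed by -1.31 ± 0.44, Atp6v1h by 1.64 ± 0.47, Thada by -2.86 ± 0.84, Trim27 by -1.78 ± 0.53, the transcription factor gene Nfatc2 by 2.73 ± 0.87 and the lymphocyte GTPase gene Gimap4 by -1.09 ± 0.35 (adjusted p = 0.999 for each). Exocrine markers fell as a list (camera adjusted p = 0.00425, 0 of 13 members positive, 0 passing adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.819), without Lag3 islet 2 (0.31) and without Wt islet 1a (0.273). In NDL this list summed to at most 0.374 CPM in any library. The averaged call therefore mainly restates the islet comparison and shows no effect common to both tissues. The other lists had adjusted p-values from 0.154 to 0.988. Median, mean and test differed in sign for Treg identity, effector Tregs, IL-2 and STAT5, proliferation, early TCR, cytokine, chemokine, apoptosis, heat shock and B cell lists. With limma 0 genes passed (400 at an unadjusted p under 0.05, 121 higher and 279 lower, and 645 without Lag3 islet 1b), with voom weights 0 (460) and against a fold of 1.5 0 (131).

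Whether the genotype effect differed between islets and NDL was tested as a difference of differences. It was -2.15 ± 0.88 for Lag3, -6.62 ± 1.57 for the peroxisomal gene Pex2, -3.32 ± 0.87 for Azin1, an antizyme inhibitor, 2.97 ± 0.93 for Mcm7, -3.20 ± 1.08 for Cd74, -2.12 ± 0.99 for Nkg7 and 0.76 ± 0.48 for Ctla4, each with an adjusted p of 1. Exocrine markers were more negative in islets (camera adjusted p = 0.00596, 0 of 13 positive), and the estimated correlation ended this call (adjusted p = 0.897). It also ended without Lag3 islet 2 (0.204), Wt islet 1a (0.238) or Wt NDL 1a (0.0898), without the 1b columns (0.215) and without the 3 libraries scaled up (0.447). With the exocrine list at or under 0.374 CPM in every NDL library, a genotype difference there could hardly be seen. The call therefore mainly restates the islet comparison. Proliferation (adjusted p = 0.611) and the other lists (0.121 to 0.996) did not pass, and the effector Treg, early TCR, cytokine and interferon lists had measures of opposite sign. Genes that passed numbered 0 with limma (437 at an unadjusted p under 0.05, 107 higher and 330 lower, 686 without Lag3 islet 1b and 691 without the 1b columns), 0 with voom weights (524) and 0 against a fold of 1.5 (294). Across the 10868 genes, which are not independent replicates, the genotype differences in islets and NDL correlated at r = -0.0112.

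**Figure D2:**
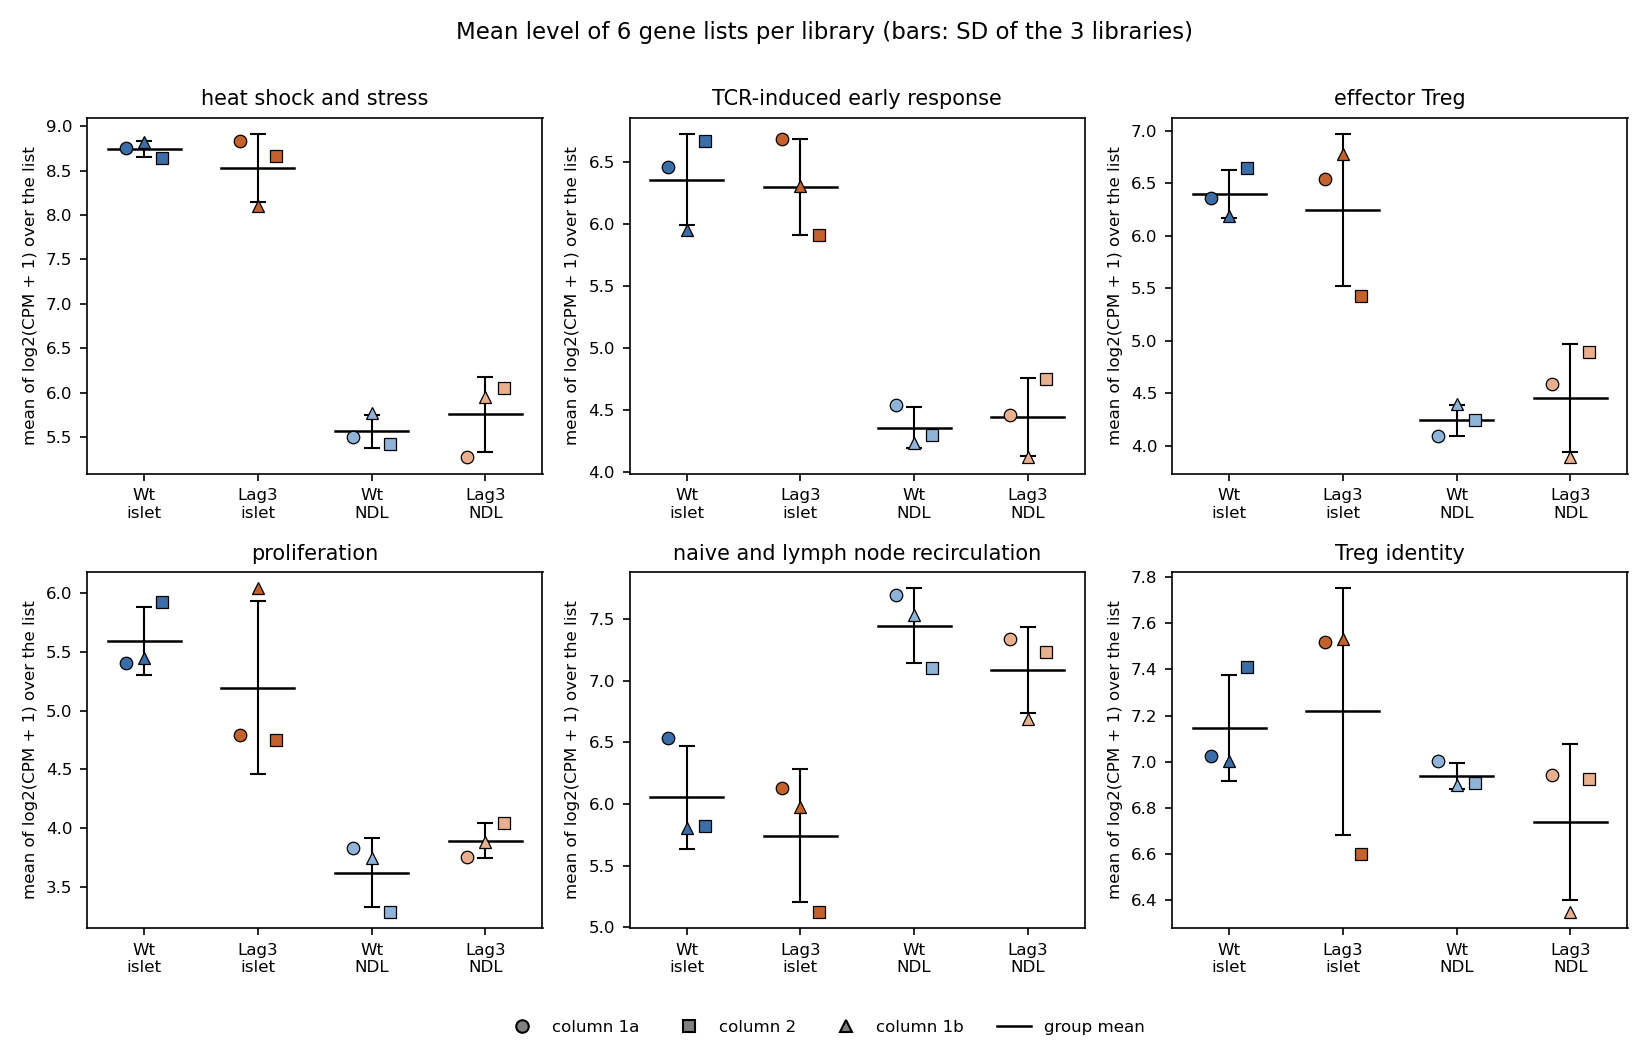
Mean log2(CPM + 1) over the members of 6 gene lists in the 12 libraries, with markers for columns 1a, 2 and 1b, horizontal lines for group means and bars for the SD (n = 3 per group). For heat shock genes the Wt islet libraries sit between 8.64 and 8.82 and the Wt NDL libraries between 5.42 and 5.77.

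Islet libraries of Tregs were then compared with NDL libraries within each genotype, to describe Tregs at the site of disease. Markers of other cells also stood higher in islet libraries, as given below. Whether a gene higher there came from Tregs or from such cells was not tested. In Wt cells 20 genes rose in islets and 0 fell. Ctla4, an inhibitory receptor central to Treg function (chromosome 1, 60887000 to 60915832, plus strand), measured 2297 ± 389 CPM in islets and 472 ± 70.1 in NDL (2.28 ± 0.34, adjusted p = 0.00241). The chemokine gene Ccl5 measured 188 ± 43.7 against 4.47 ± 2.28 CPM (5.19 ± 0.84, adjusted p = 0.00718). Rgs2, a regulator of G protein signalling, rose by 4.08 ± 0.55 (adjusted p = 0.000822), and Nfil3, a transcription factor gene induced in activated T cells, by 5.68 ± 1.14 (adjusted p = 0.0458). Effector Treg genes rose as a list (camera adjusted p = 5.74e-13, 0.0108 with an estimated correlation), with 27 of 29 members positive, 1 passing over all genes and 14 adjusted over the list alone. Il10, a suppressive cytokine, did not pass over all genes (6.02 ± 1.25, adjusted p = 0.0569), nor did the receptor gene Tigit (4.35 ± 1.28, adjusted p = 0.264). Inhibitory receptors rose (adjusted p = 1e-04, 0.014 with an estimated correlation), with 12 of 14 positive and 3 passing adjusted over the list alone, Ctla4 being the 1 that passed over all genes. The Treg identity list did not pass (adjusted p = 0.806, with 2 members higher and 1 lower adjusted over the list alone), and Foxp3, chosen after its values were seen, differed by -0.50 ± 0.40 (adjusted p = 0.869).

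Cell cycle genes were higher and genes of naive, recirculating T cells lower in Wt islet libraries than in Wt NDL libraries. The proliferation list rose (camera adjusted p = 6.26e-17, 0.00771 with an estimated correlation), with 38 of 42 members positive, a median of 2.02, 0 passing over all genes and 17 adjusted over the list alone. Mki67 measured 475 ± 213 against 85.6 ± 63.0 CPM (2.61 ± 0.67, adjusted p = 0.177), Top2a, a topoisomerase of dividing cells, 341 ± 34.2 against 87.5 ± 50.2 CPM (2.12 ± 0.54, adjusted p = 0.163), and Stmn1 531 ± 236 against 104 ± 36.3 CPM (2.32 ± 0.54, adjusted p = 0.107). The naive and recirculation list fell (adjusted p = 2.16e-09, 0.014 with an estimated correlation, median -1.36), with 2 of 13 members positive, 0 passing over all genes and 7 lower adjusted over the list alone. The repressor gene Bach2 measured 7.59 ± 4.49 against 137 ± 48.2 CPM (-4.07 ± 0.86, adjusted p = 0.0639), Satb1 147 ± 31.0 against 425 ± 36.2 CPM and Lef1, a factor of naive T cells, 237 ± 107 against 593 ± 29.8 CPM. The chemokine and integrin list rose (adjusted p = 3e-07, 0.0141 with an estimated correlation), with 17 of 22 positive, 1 passing over all genes and 8 adjusted over the list alone, and Ccr2, a receptor for inflammatory chemokines, differed by 1.89 ± 0.52 (adjusted p = 0.222). IL-2 and STAT5 genes fell slightly (adjusted p = 0.0123, 0.0331 with an estimated correlation, median -0.38), with 8 of 23 positive and 0 passing either way. Among them the survival gene Bcl2 differed by -1.80 ± 0.61 and Prdm1, which encodes Blimp1, by 3.31 ± 1.24. Glycolysis genes rose (adjusted p = 0.0123, 14 of 17 positive, 0 passing adjusted over the list alone), and this call was lost with an estimated correlation (adjusted p = 0.127). Effector T cell cytokines (adjusted p = 0.407), the interferon response (0.834), apoptosis regulators (0.407) and stroma markers (0.708) did not pass, and for the interferon list the test was negative and the median positive.

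Stress and early activation genes were among the largest differences between Wt islets and Wt NDL. Hspa1b, an inducible Hsp70 gene on chromosome 17, was at 1972, 1421 and 1411 CPM in Wt islet libraries 1a, 2 and 1b and listed at 0 in all 3 Wt NDL libraries. Hspa1a, its near-identical neighbour, measured 809 ± 256 CPM in islets and was at 0.0614, 0 and 0 CPM in NDL. Reads shared by these copies cannot be told apart, so their separate levels are uncertain. The cochaperone gene Dnajb1 rose by 3.68 ± 0.52 (adjusted p = 0.00152) and Hsp90aa1 by 1.96 ± 0.37 (adjusted p = 0.0327). The heat shock list rose (adjusted p = 7.04e-22, 0.0041 with an estimated correlation), with 11 of 12 members positive, 4 passing over all genes and 10 adjusted over the list alone. Early TCR response genes rose too (adjusted p = 2.19e-10, 0.0041 with an estimated correlation), with 15 of 20 positive, 3 passing over all genes and 8 adjusted over the list alone. Of these, the AP-1 genes Fos (chromosome 12, 85473890 to 85477273, plus strand) and Jun rose by 7.03 ± 0.75 (adjusted p = 4.83e-05) and 6.47 ± 1.16 (adjusted p = 0.0222), and the phosphatase gene Dusp1 by 4.43 ± 0.55 (adjusted p = 0.000335).

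Markers of other cells also stood higher in Wt islet libraries. The summed level of exocrine markers was 181 to 3362 CPM in Wt islets and at most 0.362 CPM in Wt NDL. The list rose (adjusted p = 9.24e-23, 0.0253 with an estimated correlation, 13 of 13 positive), with 13 passing adjusted over the list alone and 1, Ctrb1, over all genes. B cell markers rose (adjusted p = 3.44e-06, 0.0331 with an estimated correlation), with 7 of 8 positive, 5 passing adjusted over the list alone and 1, Cd74, over all genes at 290 ± 87.7 against 23.6 ± 20.2 CPM (4.20 ± 0.76, adjusted p = 0.0242). Cd74 is also made by activated lymphocytes and other antigen-presenting cells. The tested myeloid markers rose (adjusted p = 0.00289, 0.0253 with an estimated correlation, 6 of 6 positive, 0 passing either way). These were 6 of 14 listed symbols, and Csf1r, Itgam, Itgax, C1qa, C1qb, C1qc and Emr1 fell below the filter. Of the B cell list 8 of 14 symbols were tested, with Pax5, Blk and Ebf1 below the filter. Calls were lost with an estimated correlation for CD8 and NK markers (adjusted p = 0.0146, then 0.051), of which Nkg7 passed over all genes (3.60 ± 0.70, adjusted p = 0.0373), and for the 2 endocrine markers tested (0.0047, then 0.0848). Genes chosen after their values were seen complete the 20. They were Igj, the immunoglobulin joining chain (445, 531 and 213 CPM in islets against 0, 0.121 and 0.145 in NDL libraries 1a, 2 and 1b), Cybb, a phagocyte oxidase subunit, at 6.49 ± 1.21, Amy2b, a pancreatic amylase, at 4.55 ± 0.90, Rgs1 at 1.95 ± 0.37, AW112010 at 1.85 ± 0.38, and the exocrine gene Zg16, listed at 0 in all Wt NDL libraries.

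**Figure D3:**
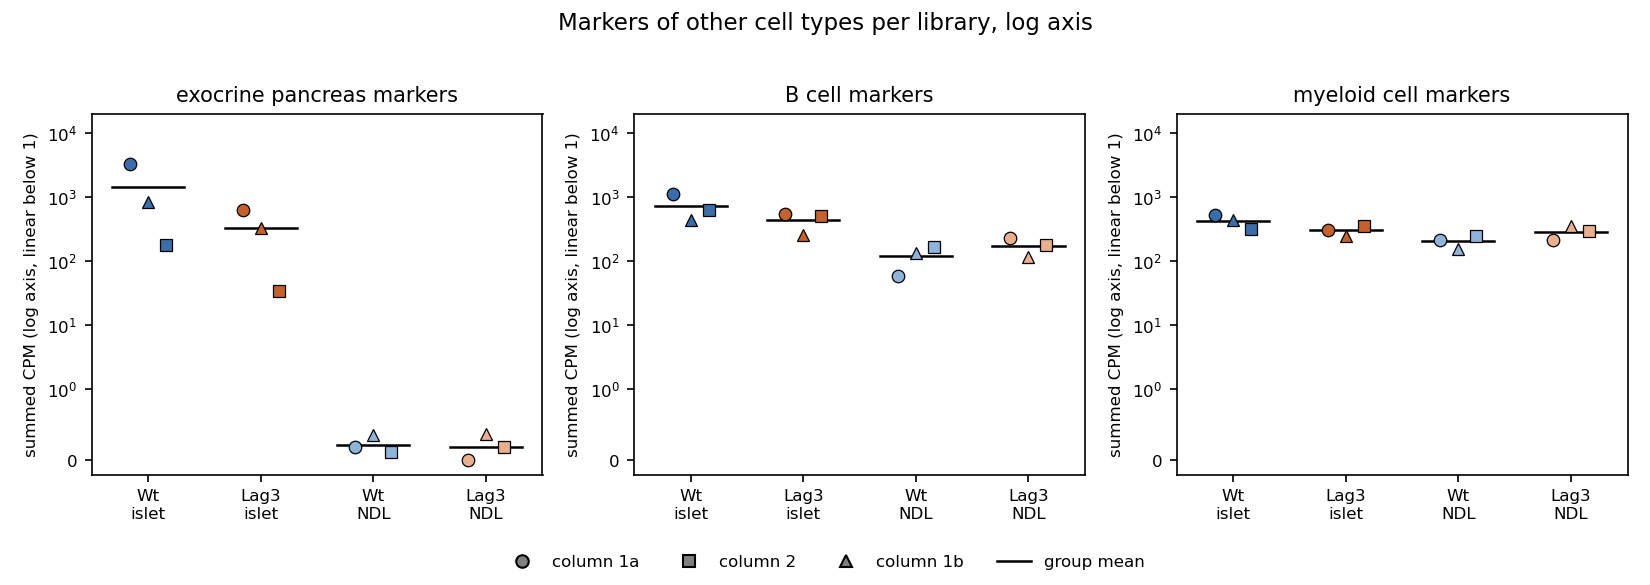
Summed CPM of exocrine, B cell and myeloid markers in the 12 libraries on a log axis that is linear below 1 CPM, with markers for columns 1a, 2 and 1b and horizontal lines for group means (n = 3 per group). Exocrine markers lie at 34.1 to 3362 CPM in islet libraries and at or under 0.374 CPM in NDL libraries.

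At an unadjusted p under 0.05 the Wt comparison of tissues held 818 genes (544 higher, 274 lower). The 20 that passed became 51 with voom weights (43 higher, 8 lower) and 32 with the groups of the comparison alone. They became 11 with no filter, 11 with the replicate number as a block, 10 against a fold of 1.5 and 8 without the 1b columns. Hspa1b, Hspa1a, Fos, Dusp1, Igj, Rgs2, Dnajb1 and Ctla4 passed whichever library was left out. Without Wt islet 1a 9 genes passed, and the other 12 of the 20 had adjusted p-values from 0.131 for Ccl5 to 0.263 for Nfil3. Without Wt islet 1b, Wt NDL 1a, Wt NDL 2 or Wt NDL 1b 11 genes passed.

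In Lag3-deficient cells 13 genes rose in islets against NDL and 0 fell. Ctla4 measured 2545 ± 778 CPM in islets and 307 ± 88.8 in NDL (3.04 ± 0.34, adjusted p = 8.77e-05). Il10 (chromosome 1, 131019845 to 131024974, plus strand) was at 284, 33.1 and 189 CPM in islet libraries 1a, 2 and 1b and at 0, 0 and 0.0748 CPM in NDL (adjusted p = 0.0245). Rgs2 rose by 4.11 ± 0.55 (adjusted p = 0.000896), Rgs1 by 2.03 ± 0.37 (adjusted p = 0.0245) and the transcription factor gene Klf6 by 3.32 ± 0.62 (766 ± 264 against 98.2 ± 68.9 CPM, adjusted p = 0.0307). Effector Treg genes rose as a list (camera adjusted p = 6.31e-12, 0.0174 with an estimated correlation), with 24 of 29 members positive, 1 passing over all genes and 11 adjusted over the list alone. Proliferation genes rose (adjusted p = 1.83e-11, 0.0201 with an estimated correlation), with 37 of 42 positive, 0 passing over all genes and 8 adjusted over the list alone. Within it Ube2c, a mitotic ubiquitin-conjugating enzyme, differed by 3.21 ± 0.68 (adjusted p = 0.0725), Top2a by 2.37 ± 0.54 (adjusted p = 0.108) and Mki67 by 1.26 ± 0.67 (adjusted p = 0.613). Chemokine and integrin genes rose (adjusted p = 8.48e-06, 0.0376 with an estimated correlation), with 18 of 22 positive, 0 passing over all genes and 6 adjusted over the list alone, and Ccr2 measured 201 ± 28.3 against 38.1 ± 6.34 CPM (2.37 ± 0.52, adjusted p = 0.0906).

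Stress and early response genes rose in Lag3-deficient islet libraries as well. The heat shock list (adjusted p = 2.4e-20, 0.00333 with an estimated correlation) had 11 of 12 positive members, 3 passing over all genes and 9 adjusted over the list alone, and the early TCR response list (adjusted p = 1.07e-11, 0.00333 with an estimated correlation) had 17 of 20, 2 and 10. Hspa1a and Hspa1b, with the same doubt over shared reads, had adjusted p = 3.87e-06, Fos rose by 6.37 ± 0.75 (adjusted p = 0.000171), Dusp1 by 3.29 ± 0.55 (adjusted p = 0.011), Hsp90aa1 by 1.93 ± 0.37 (adjusted p = 0.0436) and Ppp1r15a, a stress-induced phosphatase subunit, by 5.54 ± 0.86 (261 ± 32.0 against 6.97 ± 6.08 CPM, adjusted p = 0.00586). Igj (adjusted p = 0.0103) and Hmbox1 (4.39 ± 0.77, adjusted p = 0.0182), both chosen after their values were seen, complete the 13.

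Other lists that passed in Lag3-deficient cells at the preset correlation were lost with the estimated one, and of these inhibitory receptors (adjusted p = 0.0302) and naive and recirculation genes (0.0157) passed with fry. Higher in islets were Treg identity (adjusted p = 0.0179, then 0.222), inhibitory receptors (0.00404, then 0.0521), glycolysis (0.0179, then 0.189), endocrine (0.0407, then 0.222), exocrine (1.76e-10, then 0.145), B cell (0.0301, then 0.24) and myeloid markers (0.0179, then 0.0747), and at most 2 members of each passed adjusted over the list alone. Lower were naive and recirculation genes (0.000149, then 0.0765), with 2 of 13 members positive and 5 lower adjusted over the list alone. IL-2 and STAT5 signalling (adjusted p = 0.696), effector cytokines (0.174), the interferon response (0.39), apoptosis regulators (0.929), CD8 and NK markers (0.996) and stroma (0.161) did not pass, and all of these but cytokines and stroma had measures of opposite sign.

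At an unadjusted p under 0.05 this comparison held 947 genes (372 higher, 575 lower), and 1544 without the 1b columns. When the second deposited table was used, 31 genes passed, 26 higher and 5 lower, against 13 and 0 here. There were 36 with voom weights (33 higher, 3 lower), 26 with RLE, 23 without the 1b columns (14 higher, 9 lower), 8 with the groups of the comparison alone and 7 with no filter. Hspa1a, Hspa1b, Ctla4, Fos, Rgs2 and Ppp1r15a passed whichever library was left out. Igj did not without Lag3 islet 2 (adjusted p = 0.108), Dusp1 without Lag3 islet 2 or Lag3 NDL 2 (up to 0.0721), Hmbox1 without any 1 of the Lag3-deficient NDL libraries (up to 0.134), Klf6, Il10, Rgs1 and Hsp90aa1 without Lag3 islet 1a, Wt islet 1a, Wt islet 2 or, for each, some others (up to 0.139, 0.152, 0.118 and 0.191). Without Lag3 islet 1b 32 genes passed, 14 higher and 18 lower.

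Of the 20 and 13 genes higher in islets, 9 were shared by the genotypes (Ctla4, Dusp1, Fos, Hsp90aa1, Hspa1a, Hspa1b, Igj, Rgs1 and Rgs2), where 0.0239 would be shared if the lists were independent. The comparisons use separate libraries but the same estimate of each gene's spread, so their calls are not independent. Across genes, the tissue differences in Wt and Lag3-deficient cells correlated at r = 0.293, and at r = 0.321 over the 5612 genes with an average log2 level of at least 4. A gene that passed in only 1 genotype is not shown to differ between genotypes, as 0 genes passed the test of that difference.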

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

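The tests of exocrine RNA and of handling for the heat shock genes, and of the correlation between exocrine genes, were chosen only after the results they bear on were seen.

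Exocrine marker genes were the 1 list that passed the test of whether the genotype difference was the same in islets and NDL. That test gave a camera adjusted p of 0.00596, with 0 of 13 members positive, and over the alternatives tried the adjusted p ran from 3.67e-08 to 0.897. Of 100 splits of the libraries 57 called as many lists, 1 for the real split and up to 3 for others, so chance cannot be excluded. In NDL its summed level was at most 0.374 CPM in any library, so the test of the difference mainly restates the islet comparison. Within islets the list was lower in Lag3-deficient libraries (adjusted p = 3.24e-05). Leaving out 1 islet library raised the adjusted p to as much as 0.123, without Lag3 islet 2, and to 0.109 without Wt islet 1a. The 13 genes vary together between libraries, with an estimated correlation of 0.835, and with it the adjusted p was 0.959. List means were 7.78, 3.16 and 5.75 log2 units in Wt islet libraries 1a, 2 and 1b. They were 4.93, 0.731 and 3.91 in Lag3-deficient ones, the same order, and lower than Wt under each number. The numbers were not taken as pairs, so spread shared by a number counts as noise in these tests. The differences may reflect how much pancreatic RNA single libraries held, while an effect of the genotype stays open and untested apart from this.

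The mean of the heat shock list was higher in every islet library than in every NDL library of both genotypes. Carry-over of exocrine RNA would have to bring the heat shock genes with it, yet over the 6 islet libraries the highest and lowest summed level differed 1.66-fold for the heat shock list and 98.6-fold for the exocrine list, which argues against that source. The labels do not describe handling, and any difference in it between islets and lymph nodes would coincide with tissue in all 12 libraries. Such handling cannot be told apart from an effect of the tissue on the cells. The gap between the lowest islet and the highest NDL library was 2.05 log2 units, which both would give. The same limit applies to every difference between islets and NDL given here, including Ctla4 and the effector Treg, proliferation and naive lists. Fos, Jun, Dusp1 and other early response genes in particular read handling as well as TCR signals.

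No gene passed a genotype test with limma on all libraries (624, 296 and 400 at an unadjusted p under 0.05 in islets, in NDL and averaged, 0 with voom weights in each). Genes did pass in islets when Lag3 islet 1b was left out. A shift of the 1b columns common to all groups is argued against as the main source of spread. With that set as a term, the residual variance of the median gene was 1.04 times its value without it. This term cannot show a 1b difference confined to some groups or genes, which was not tested. The spread between libraries of a group may be enough to hide changes in single genes. In the islet comparison 0% of simulated 2-fold, 14.5% of 4-fold and 50.5% of 8-fold changes passed. The genes changed there all had an average log2 level of at least 4. On average the 3 libraries scaled up from fewer reads deviated more from their group means than the other 9, by a ratio of 1.22. They may add to the spread between libraries. Their median deviations were 0.778 (Lag3 islet 2), 0.794 (Lag3 NDL 1b) and 0.596 log2 units (Wt NDL 2). These did not follow the scaling factors of 2.79, 1.11 and 1.58, and the other 9 libraries ran from 0.534 to 0.701. An effect of the genotype on single transcripts, small or large, therefore stays open.

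Other splits of the same libraries bear on each count. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In those, the real and the highest other count were 0 and 3 genes for the genotypes in islets (10 of 10 splits as large), 0 and 0 in NDL (10 of 10), 20 and 0 for the tissues in Wt (1 of 10) and 13 and 1 in Lag3-deficient cells (1 of 10). For lists they were 1 and 2 (6 of 10), 1 and 1 (3 of 10), 14 and 7 (1 of 10) and 13 and 7 (1 of 10). With 100 splits drawn, chance could not be excluded for the lists of the genotype averaged over tissues (1 and 3 lists, 62 of 100). The gene counts averaged over tissues and for the difference of the genotype effect were 0 and 0 (100 of 100 in each). Any split is at least as large as a count of 0, so the splits for counts of 0 bear on nothing.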

How the results depend on the processing

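Tests on pseudocounts, unscaled totals, the 1b columns and the 3 libraries scaled up, the list tests on the second table, and the tissue comparison averaged over genotypes with all its alternatives, were chosen only after the data were seen. Planned count-model tests were not run, since the values are not counts. No list, and no named gene in the values counted below, passed in opposite directions, and causes were not tested unless named. Genes passing a genotype test stayed at 0 in NDL, averaged and for the difference under every alternative, and in islets except without Lag3 islet 1b (16), so omissions ranged from 0 to 16. Wt islet against NDL (20 genes) gave 11 with no filter (more genes tested), 32 with its own groups alone, 51 with voom weights, 10 against a fold of 1.5 and 8 without the 1b columns (fewer libraries), and 9 (without Wt islet 1a) to 24 with 1 library left out. Lag3-deficient islet against NDL (13) gave 26 with RLE, 7 with no filter, 8 with its own groups, 36 with voom weights, 31 with the second table and 23 without the 1b columns (14 higher, 9 lower), and 9 to 32 (without Lag3 islet 1b, 14 higher and 18 lower) with 1 left out. The averaged tissue comparison (100) gave 40 with no filter, 218 with voom weights, 28 against a fold of 1.5, 45 without the 1b columns, and 65 (without Wt islet 1a) to 109 with 1 left out. Lists passing in islets between genotypes (1) numbered 0 with an estimated correlation, fry, no 1b columns or no scaled-up libraries and 2 with the second table, the same as averaged over tissues, with 0 (without Lag3 islet 2 or Wt islet 1a) to 1 for omissions in both. In NDL (1) they were 0 with the estimated correlation, fry, a filter of 50 and the second table, and 0 (without Lag3 NDL 1a, Wt NDL 1a or Wt NDL 1b) to 2 with 1 left out. Without the 1b columns or the scaled-up libraries the 1 passing list there was another, B cell markers, with the CD8 and NK list at adjusted p = 0.138 and 0.0591. For the difference (1) they were 0 with the estimated correlation, fry and no 1b columns, 2 with RLE, and 0 (without Wt islet 1a or Wt NDL 1a) to 2, and without the scaled-up libraries or Lag3 islet 2 the exocrine list was not among those passing (0.447 and 0.204). In Lag3-deficient islet against NDL (13) they were 5 with the estimated correlation and 7 with fry (10 to 13 for omissions), and in Wt (14) 11 to 14. The Lag3 difference in islets was -4.06 and -1.08 with pseudocounts of 0.25 and 4, and -2.44 to -2.33 for omissions that left it tested. Over the 505 results for named genes, 7024 alternative values kept direction and side of the threshold, 112 differed in sign or lay at 0 on 1 side with no pass either way, 66 passed newly and 60 no longer passed. With the replicate number as a block, 11 genes passed in Wt islet against NDL and 12 in Lag3-deficient islet against NDL, and no other count moved by over 1.5 times. The labels name nothing that libraries with the same number share, and their deviations correlated at -0.0857 to 0.157, so the numbers were not taken as pairs. As a hint from the data only, 9 of 12 libraries correlated best with their own number. In each other group 1 of the 3 libraries carried that number, so fewer would be likely by chance. Between scalings (TMM, RLE, totals and the second table) the median of all genes ran from -0.22 to 0.01 between genotypes in islets, from -0.26 to 0.02 between tissues in Lag3-deficient cells and from -0.25 to 0.02 for the difference. Depth before scaling is known for 5 libraries, so no floor could be set for genes listed at 0. The median SE of a gene was 1.06 log2 units, and 0.415 for genes with an average log2 level of at least 8.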

Other observations

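The comparison of tissues averaged over genotypes (6 islet against 6 NDL libraries) and its splits were chosen only after the data were seen, and the genes named from it were chosen after their values were seen.

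In both genotypes combined, 100 genes passed with limma, 89 higher and 11 lower in islet libraries, and 48 of them stand in none of the 19 lists. The 89 include 9 exocrine markers, the digestive enzyme gene Amy2b and the zymogen granule gene Zg16, the B cell marker Cd74 and the CD8 and NK cell marker Nkg7. They also include the immunoglobulin joining chain gene Igj at 317 ± 206 against 0.568 ± 1.23 CPM (adjusted p = 1.04e-05). Cybb, the phagocyte oxidase subunit gene, is another, at 99.7 ± 43.5 against 0.737 ± 1.57 CPM (adjusted p = 0.000767). Among the 48 were Klf6 (2.64 ± 0.44, adjusted p = 0.00417), the stress-induced gene Ppp1r15a (4.58 ± 0.61, adjusted p = 0.00039), the hypoxia factor gene Hif1a at 353 ± 87.1 against 116 ± 29.5 CPM (1.59 ± 0.31, adjusted p = 0.0144), Id2, an inhibitor of helix-loop-helix factors, at 173 ± 22.7 against 44.0 ± 10.8 CPM (1.97 ± 0.37, adjusted p = 0.0098), and the polyamine enzyme gene Odc1 at 468 ± 186 against 126 ± 40.3 CPM (adjusted p = 0.0098). Srgn, a granule proteoglycan, measured 1471 ± 383 against 601 ± 138 CPM (adjusted p = 0.0144) and the endoplasmic reticulum chaperone Hsp90b1 1277 ± 170 against 492 ± 140 CPM (adjusted p = 0.00748). For each of these, every islet library lay above every NDL library. The NF-kB pathway gene Malt1 (147 ± 56.1 against 38.3 ± 16.1 CPM, adjusted p = 0.0456) and Tnfaip3, which restrains it (3.72 ± 0.79, adjusted p = 0.023), were higher too. Lower in islets were the receptor gene Gpr83 at 41.4 ± 20.2 against 162 ± 33.3 CPM (-2.03 ± 0.40, adjusted p = 0.0144), Tmem59 at 133 ± 64.4 against 355 ± 63.0 CPM (adjusted p = 0.0212), Bach2 (-3.19 ± 0.61, adjusted p = 0.0125) and Igfbp4 (-4.48 ± 0.92, adjusted p = 0.0191).

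Within the lists, 8 proliferation genes passed over all genes and 21 adjusted over the list alone, among them Top2a (2.25 ± 0.38, adjusted p = 0.00522), Ube2c (2.69 ± 0.48, adjusted p = 0.00759) and Hmgb2 at 1118 ± 366 against 407 ± 147 CPM (adjusted p = 0.0144). Of effector Treg genes 8 passed over all genes and 17 adjusted over the list alone, among them Maf (1.96 ± 0.41, adjusted p = 0.02), Lgals1 (1.15 ± 0.26, adjusted p = 0.0364), the tissue repair factor Areg (5.09 ± 0.93, adjusted p = 0.00855) and Fgl2 (4.30 ± 0.85, adjusted p = 0.0151). Ccr2 measured 182 ± 27.4 against 41.2 ± 9.37 CPM (adjusted p = 0.00613) and Cxcr4 rose by 2.87 ± 0.58 (adjusted p = 0.0172). Of 100 splits of the 12 libraries, 1, the real one, gave as many genes, and the highest other gave 1. A chance division of these libraries is therefore unlikely to give this count. Chance differences between animals are not excluded by the splits, since the replicates may be technical. Without Wt islet 1a 65 genes passed, with voom weights 218, without the 1b columns 45, with no filter 40 and against a fold of 1.5 28. When the second deposited table was used, 107 were higher and 31 lower, and with totals as deposited 82 and 24, against 89 and 11 here.

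Genes that pass between genotypes in islets only without Lag3 islet 1b are more often those in which 1b lies apart from 1a and 2, by the way they are selected. Among the 16 that passed so, Unc50 was listed at 0 in libraries 1a and 2 and at 131 CPM in 1b, Ndufv2, a subunit of respiratory complex I, measured 19.0, 32.5 and 244 CPM in 1a, 2 and 1b, and N6amt2 9.87, 16.0 and 136 CPM, where the Wt islet libraries held 124 to 139 CPM. Hmbox1, another of the 16, measured 18.9, 16.0 and 28.5 CPM. These genes were chosen after their values were seen.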
